A study of Homo sapiens with 24 samples.

How the data were processed

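Gene expression was measured on Affymetrix HTA2.0 arrays in WI-38 cells, which are human lung fibroblasts. They were transduced with a fusion of oncogenic RAS to the oestrogen receptor (ER:RAS) that 4-hydroxytamoxifen (4OHT) switches on. Per the labels' protocols, the cells grew in DMEM with 10% FBS and 3% oxygen. Oncogene-induced senescence (OIS) was started with 400 nM 4OHT, and quiescence by moving cells to 0.2% FBS. At each time 500000 cells were collected, RNA was extracted with a column kit (RNeasy Plus), and 100 ng of total RNA was labelled with the WT PLUS kit, per the labels' protocols.

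The values are the authors' deposited log2 expression values, with 41249 rows and 24 columns, rounded to 1 decimal and lying between 0.3 and 14.1. Per the submitters' processing notes they were made with RMA in the oligo package, which corrects background, normalizes by quantiles and summarises probes. The versions, whether all arrays went through 1 run, and how the rows were chosen are not given in the sources used here. The median of every array was 6.2 or 6.3, and detection p-values were not used here. Absolute RNA amounts are lost in such a normalization, so each change is relative to the other rows of the array. The number of arrays limits the precision.

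Array rows were named from the platform annotation of the table's probes, updated to current symbols with the synonyms of a RefSeq gene table (GRCh38.p14, used for names and transcript lengths). Of the rows, 18793 carried 1 gene symbol, 1270 carried several and 21186 had none listed. Of those with 1 symbol, 18577 were current, 212 were updated through a synonym and 4 were kept as given. They stand for 17749 genes. A row with several symbols was named for none of them. For a gene with several rows, the row with the highest mean over all arrays was used. In all 24 columns, 1352 rows were identical to an earlier row, and every row stayed in the counts.

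Groups are treatment by time: 6 times in each series, with 2 arrays a group that the labels call biological replicates. The labels do not say whether replicates came from separate thaws or transductions, so p-values measure the spread between these samples. Before testing, the arrays of each group were compared. A pair whose difference had an SD under 1.5 times that of rounding alone (0.0408) was to count as 1 sample. This applied to OIS 96 h, whose columns were replaced by their mean, leaving 23 columns in 12 groups.

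All comparisons came from 1 linear model with a mean per group, fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3 on the log2 values, with 11 residual degrees of freedom and 3.70 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 41249 rows of a comparison, and a row was called at an adjusted p under 0.05. A moderated F-test over the 5 comparisons with 0 h asked for a change at any time. A row was OIS-specific at 96 h if it was called against 0 h in the OIS series and called in the same direction in the OIS change minus the quiescence change. A row was shared if it was called in the same direction in both series.

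The groups of genes were 25 lists and 6 sets of cell type markers, taken from general knowledge of senescence, RAS signalling, serum deprivation and fibroblasts. Each list was tested with limma's camera, with an inter-gene correlation of 0.01, adjusted over 75 tests (25 lists in 3 comparisons). Of these tests 41 passed, and 1 still passed with an estimated correlation, the ERK feedback and target genes in the difference between the series. With fry, which asks only whether the members of a list move on balance in 1 direction, 56 passed. Genes are named by a fixed rule. In each of 3 comparisons (OIS 144 h, quiescence 96 h, the difference at 96 h) these were the 8 largest rises and the 8 largest falls among called rows with 1 symbol in which the later arrays lay all above or all below those of 0 h (for the difference, the OIS changes by replicate number above or below the quiescence changes). To these were added up to 4 called members of each list with the largest change, and fixed markers of senescence, cell cycle and RAS signalling whatever their values. A member that goes against most of its list could be named too. The groups, comparisons, tests, lists, the naming rule and the alternatives listed below were set before the data were examined. The rule for near-equal pairs was chosen afterwards, as were 3 more alternatives: all 24 arrays, identical rows counted once, and 72 h in place of 96 h.

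The steps were tested on simulated data drawn for the 41249 rows, with 50 rows changed at each of 4 folds. For OIS 144 h, 8 of 50 rows changed by 1.25-fold were recovered, 35 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold. For quiescence 96 h the numbers were 13, 36, 46 and 48. For the difference at 96 h they were 1, 17, 37 and 47. False calls numbered 7 of 154, 8 of 161 and 1 of 104 called rows, which include members of a shifted list. In each comparison camera called the 1 shifted list of 20 genes and none of the other lists. The simulated rows were drawn independently of each other, whereas the estimated correlation within the real lists reached 0.659 (G2/M and mitosis genes). The simulation therefore does not show how often camera calls correlated lists falsely. Far fewer rows changed in the simulation than were called in the data (22591 for OIS 144 h). The Benjamini-Hochberg limit depends on that number. The numbers recovered and the false calls therefore hold for the simulated setting only, not for the real comparisons.

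Alternatives were another quantile normalization, centring on array medians, leaving out dim rows, an intensity trend with robust eBayes, array weights, stricter thresholds, treat, 1 row per gene, each series alone, the replicate number as a block, and leaving out each array in turn. Values were handled with version 1.17.8 of data.table and drawn with matplotlib 3.10.9 in Python 3.11.15. Cells with 4OHT and no ER:RAS were not analysed here.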

Results

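The arrays followed WI-38 fibroblasts with 4OHT-inducible ER:RAS through oncogene-induced senescence (OIS), before 4OHT (0 h) and after 24, 48, 72, 96 or 144 h of it, and through serum deprivation, before it and after 12, 24, 48, 72 or 96 h. The study divides the OIS series into a proliferative stage (0 h), a hyperproliferative stage (24 and 48 h), an initiation stage (72 and 96 h) and an establishment stage (144 h). Quiescence, a growth arrest that cells can leave, was included to find what is specific to OIS. Each group held 2 arrays. Neither series had untreated arrays after 0 h, so changes from 0 h cannot be told apart from those that come with time in culture. The SD over rows of the difference between the arrays of a group was 0.119 to 0.203 in 11 of the 12 groups. At OIS 96 h it was 0.0486, against 0.0408 from rounding alone, and 77.2% of rows were equal in both columns, against 26.3% to 40.5% in the other groups. These columns differed by little more than rounding and were counted as 1 sample, so every value at OIS 96 h has n = 1 and takes its error from the spread within the other groups.

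**Figure D1:**
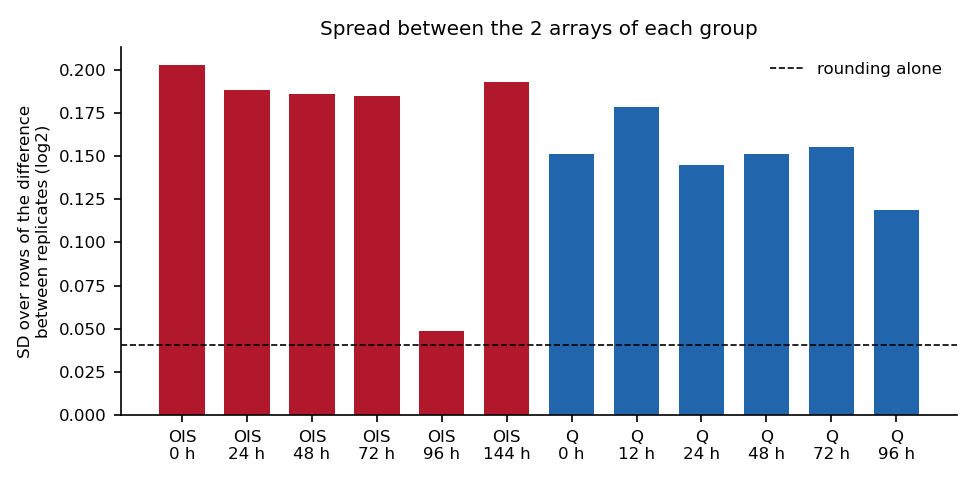
Standard deviation over 41249 rows of the log2 difference between the 2 arrays of each group (bars; red, OIS; blue, quiescence), with the level that rounding to 1 decimal gives (dashed line). The bar of OIS 96 h, at 0.0486, lies close to that line, and the other bars lie between 0.119 and 0.203.

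After 144 h of RAS induction the inflammatory cytokines IL1B and IL1A were among the genes with the largest rises. IL1B rose by 6.95 ± 0.15 log2 units (SE, n = 2 arrays in each group, 124-fold), from a level of 6.05 at 0 h, and IL1A by 6.35 ± 0.15 (81.6-fold), with adjusted p = 2.76e-13 and 1.26e-12 in limma. The other large rises were those of LCE2A (6.25 ± 0.45) and LCE1F (5.30 ± 0.13), genes of the skin's cornified envelope, the TNF-family cytokine TNFSF15 (6.15 ± 0.17), the cysteine protease inhibitor CST4 (5.15 ± 0.18), the vascular ligand ANGPT2 (4.60 ± 0.20) and the hyaluronan synthase HAS2 (4.25 ± 0.29). The 8 largest falls were those of LBH (-4.05 ± 0.08), the chromatin protein HMGB2 (-3.90 ± 0.11), the mitotic kinase PBK (-3.90 ± 0.20), the proliferation marker MKI67 (-3.80 ± 0.21), the spindle protein NUSAP1 (-3.80 ± 0.17), the cytokinesis scaffold ANLN (-3.80 ± 0.18), the hyaluronan-binding protein CEMIP (-3.80 ± 0.08) and DTL (-3.75 ± 0.19), which directs replication proteins to degradation in S phase. In all, 22591 of 41249 rows were called, 11976 higher and 10615 lower, and 10165 of 17749 genes, 5932 higher and 4233 lower. At 2-fold or more there were 2806 called rows, 1329 higher and 1477 lower. The value of LCE2A was 5.30 without OIS 144 h replicate 2 and 7.20 without OIS 144 h replicate 1.

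Cell cycle genes fell as groups. All 39 measured genes of G2/M and mitosis fell, with a median of -2.70 (camera adjusted p = 3.13e-28, adjusted p = 0.125 with an estimated correlation, 39 adjusted over the list alone). CENPE, a kinetochore motor, changed by -3.75 ± 0.23 and CCNB1, the mitotic cyclin, by -1.65 ± 0.14. Of 35 genes of G1/S and DNA replication, 33 fell and 1 rose, with a median of -1.15 (adjusted p = 7.39e-16, adjusted p = 0.153 with an estimated correlation, 33 and 1 adjusted over the list alone). Among them, the origin licensing factor CDC6 changed by -3.40 ± 0.25, MCM10 by -3.20 ± 0.18 and the helicase subunit MCM2 by -0.80 ± 0.14. Of 17 genes of homologous recombination and the Fanconi pathway, 15 fell and 1 rose, with a median of -1.30 (adjusted p = 2.59e-08, adjusted p = 0.125 with an estimated correlation, 15 and 1 adjusted over the list alone), BRIP1 (-3.45 ± 0.10) and EXO1 (-3.10 ± 0.15) most. Of 14 replication-dependent histone genes measured on rows of their own, 11 fell and 1 rose, with a median of -1.40 (adjusted p = 1.09e-06, adjusted p = 0.0852 with an estimated correlation, 12 and 1 adjusted over the list alone). Another 13 histone genes of the list lie on rows with several symbols. Of 29 proteins of the lamina and chromatin, 23 fell and 1 rose, with a median of -0.55 (adjusted p = 3.05e-10, adjusted p = 0.0852 with an estimated correlation, 23 and 1 adjusted over the list alone). LMNB1, the B-type lamin whose loss marks senescence, changed by -2.45 ± 0.14 and the condensin subunit SMC4 by -3.65 ± 0.16. Among 6 inhibitors of cyclin-dependent kinases 3 rose and 2 fell, as they did adjusted over the list alone (adjusted p = 0.715). CDKN2B (p15) rose by 3.15 ± 0.14, CDKN1A (p21) by 0.45 ± 0.08 and CDKN2A (p16 and ARF) by 0.40 ± 0.07, and CDKN1B (p27) changed by -1.20 ± 0.10.

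SASP cytokines and ERK targets rose as groups. Of 19 cytokines and chemokines of the senescence-associated secretory phenotype (SASP), 15 rose and 2 fell, with a median of 1.40 (adjusted p = 8.34e-06, adjusted p = 0.0852 with an estimated correlation, 15 and 3 adjusted over the list alone). LIF rose by 3.90 ± 0.22, IL6 by 3.65 ± 0.37 and the neutrophil chemokine CXCL8 by 2.25 ± 0.35. The IL6 arrays at 144 h stood at 11.4 and 9.8, and the rise was 2.85 without replicate 1 and 4.45 without replicate 2. Of 21 feedback and target genes of the kinase ERK, which acts downstream of RAS, 13 rose and 2 fell, with a median of 0.60 (adjusted p = 0.00272, adjusted p = 0.0852 with an estimated correlation, 14 and 2 adjusted over the list alone). The ERK phosphatases DUSP4 and DUSP6 rose by 1.65 ± 0.10 and 1.20 ± 0.15 and the pathway inhibitor SPRED2 by 1.65 ± 0.10. Of 18 NF-kB pathway genes 8 rose and 1 fell, the same numbers as adjusted over the list alone (adjusted p = 0.0443, adjusted p = 0.588 with an estimated correlation). The adhesion molecule ICAM1 rose by 2.40 ± 0.13, and REL, a subunit of NF-kB itself, changed by -0.90 ± 0.11. Of 24 ribosome biogenesis genes 13 rose and 4 fell, both also when adjusted over the list alone (median 0.35, adjusted p = 0.0443, adjusted p = 0.612 with an estimated correlation), with POLR1B, a subunit of RNA polymerase I, up by 1.45 ± 0.08. HRAS itself differed by 0.00 ± 0.06 between 144 and 0 h. The labels do not name the RAS gene of the fusion, and 4OHT acts on the fusion protein.

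Genes of the extracellular matrix and the contractile apparatus fell. Of 35 collagens and matrix proteins, 22 fell and 4 rose, with a median of -0.50 (adjusted p = 2.01e-05, adjusted p = 0.233 with an estimated correlation, 22 and 4 adjusted over the list alone). The small proteoglycan DCN changed by -3.50 ± 0.12, COL5A2 by -2.30 ± 0.11 and elastin (ELN) by -1.65 ± 0.12. COL1A1 changed by -0.50 ± 0.17 (adjusted p = 0.0221), a call lost without OIS 0 h replicate 2 (-0.30) or OIS 144 h replicate 1 (-0.40). Fibroblast markers moved with this list. Of 9 such markers 7 fell and 1 rose, with a median of -0.50, and 4 of the 9 are also in the matrix list. Of 21 contractile and myofibroblast genes, 18 fell and 0 rose, with a median of -0.50 (adjusted p = 2.59e-08, adjusted p = 0.153 with an estimated correlation, 19 and 0 adjusted over the list alone). Smooth muscle actin ACTA2 changed by -1.70 ± 0.18, and CCN2, a target of TGF-beta and YAP, by -1.65 ± 0.17. Of 6 smooth muscle and pericyte markers 4 fell and 1 rose, and 3 of the 4 that fell are also in the contractile list. Of 20 genes of the unfolded protein response and amino acid stress 11 fell and 1 rose, the same numbers as adjusted over the list alone, with the median at -0.425 (adjusted p = 0.00176, adjusted p = 0.236 with an estimated correlation). The cystine transporter SLC7A11 changed by -1.35 ± 0.23.

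The other lists did not pass in camera at 144 h, and their members went both ways. Of 22 SASP growth factors and binding proteins 11 rose, among them the EGF receptor ligand EREG (3.15 ± 0.22) and the ERBB ligand NRG1 (3.05 ± 0.17), and 6 fell (adjusted p = 0.344). Of 13 SASP proteases and inhibitors 6 rose and 3 fell (adjusted p = 0.461). MMP3 (stromelysin) rose by 1.40 ± 0.35, while collagenase MMP1 stood at 0.25 ± 0.11 (adjusted p = 0.0709), and passed without OIS 0 h replicate 1 (0.45) or OIS 144 h replicate 2 (0.40). Of 15 AP-1 and related subunits 6 rose and 5 fell (adjusted p = 0.737), with JUN up by 0.80 ± 0.11 and FOSL1 (FRA1) at -1.15 ± 0.08. Of 20 p53 targets 9 rose and 4 fell (adjusted p = 0.341), among them ZMAT3 up by 0.75 ± 0.07 and GADD45A at -1.15 ± 0.09. Of 22 FOXO targets and growth-arrest genes 6 rose, led by TXNIP (2.75 ± 0.09), and 9 fell (adjusted p = 0.166). Of 20 lysosome and autophagy genes 11 rose, led by cathepsin S (CTSS, 1.85 ± 0.08), and 4 fell (adjusted p = 0.127). Of 21 glycolysis genes 11 rose, led by ENO2 (1.60 ± 0.12), and 5 fell (adjusted p = 0.422). Of 19 genes of cholesterol synthesis and uptake 6 rose, led by the reductase DHCR7 (1.15 ± 0.15), and 4 fell (adjusted p = 0.853). Of 22 interferon-stimulated genes 9 rose and 4 fell (adjusted p = 0.789), of 16 Notch pathway genes 5 rose and 3 fell (adjusted p = 0.653), and of 12 complement genes 3 rose and 4 fell (adjusted p = 0.461). Adjusted over the list alone, 10 p53 targets rose in place of 9 and 4 complement genes in place of 3, and these other counts did not move. In fry, 8 lists that did not pass in camera passed at 144 h. These were, upwards, lysosome genes (adjusted p = 2.28e-05), p53 targets (0.000139), SASP growth factors (0.000261), CDK inhibitors (0.000317), SASP proteases (0.000991) and glycolysis (0.00342), and, downwards, FOXO targets and complement genes (0.00237 each). Of the markers of other cell types, 2 of 6 epithelial, 1 of 6 endothelial, 2 of 5 leukocyte and 0 of 4 neural markers rose, and 2, 2, 1 and 2 fell.

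**Figure D2:**
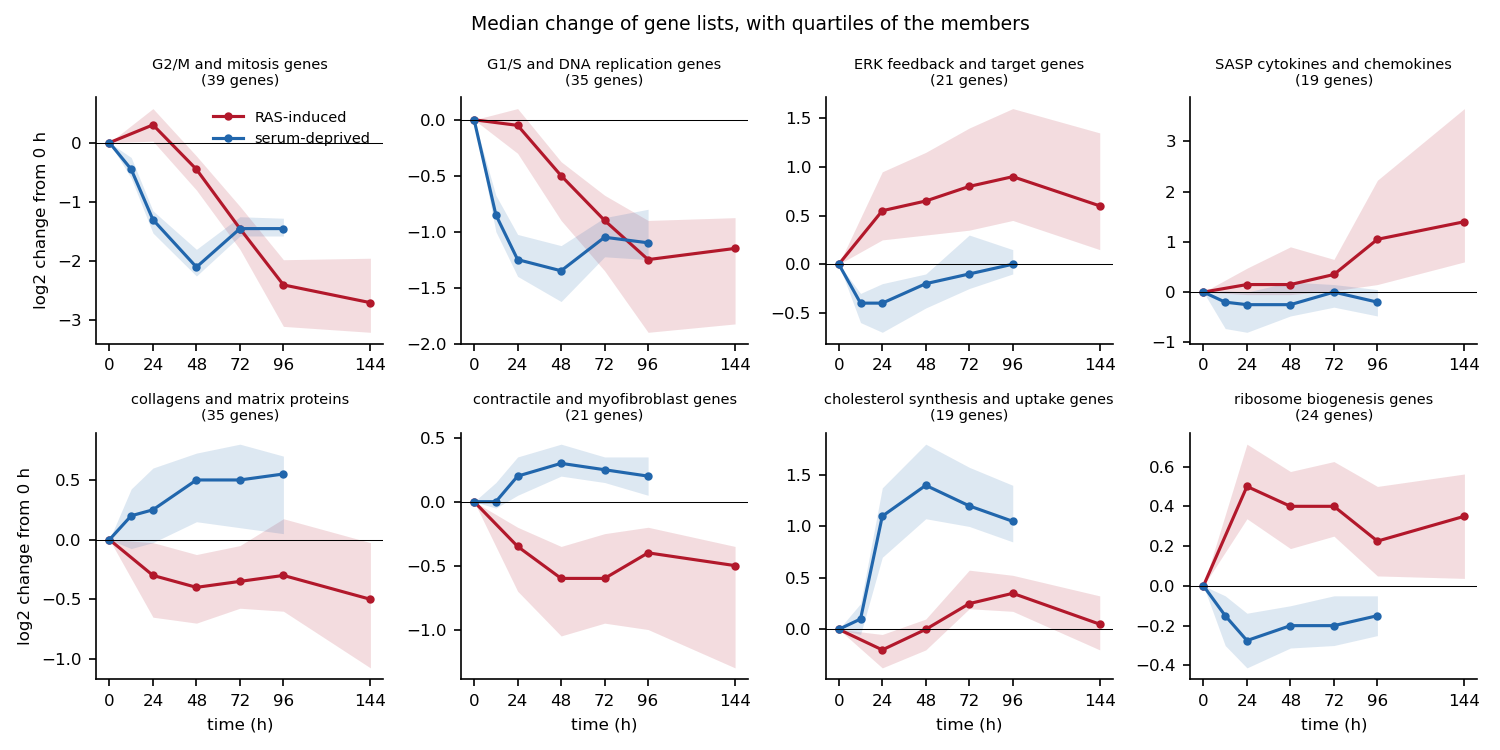
Median log2 change from 0 h of the members of 8 gene lists (lines and points) with the quartiles of the members (bands), in the OIS series (red) and the quiescence series (blue), against time in h. The G2/M and mitosis list stood at 0.30 at 24 h and -2.70 at 144 h of OIS, and at -2.10 at 48 h and -1.45 at 96 h of quiescence.

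The lists followed different courses over the OIS series, and no test of their order was run. At 24 h, 15 of 21 ERK feedback and target genes and 22 of 24 ribosome biogenesis genes were higher than at 0 h, with medians of 0.55 and 0.50, while 13 of 39 G2/M genes were higher and 0 lower. The G2/M median was -0.45 at 48 h, with 21 lower, -1.45 at 72 h, with 39 lower, and -2.40 at 96 h. MKI67, at 0.15 ± 0.21 (adjusted p = 0.653) after 24 h, changed by -0.85 ± 0.21 by 48 h and -2.00 ± 0.21 by 72 h. Of the SASP cytokines 7 were higher at 24 h, 6 at 72 h and 13 at 96 h, and 12 of 19 rose between 72 and 96 h. IL1B was up by 1.65 ± 0.15 at 24 h and 4.10 ± 0.15 at 72 h, whereas IL6 stood at -0.05 ± 0.37 (adjusted p = 0.993) and 0.40 ± 0.37 (adjusted p = 0.468) at those times and rose by 2.10 ± 0.45 at 96 h. CXCL8 and MMP3 fell before they rose, to -1.25 ± 0.35 and -2.75 ± 0.35 at 24 h. FOSL1 rose by 0.40 ± 0.08 at 24 h and lay below its 0 h level from 48 h (-0.35 ± 0.08). CDKN2B rose by 1.80 ± 0.14 at 24 h, and CDKN1A by 0.55 ± 0.08 at 72 h, after -0.20 ± 0.08 at 24 h (adjusted p = 0.0671).

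The number of rows called against 0 h was 9754 at 24 h, 10671 at 48 h, 10897 at 72 h, 12367 at 96 h and 22591 at 144 h, and 24206 rows changed at any time (moderated F-test). Between successive times 815 rows changed from 24 to 48 h, 353 from 48 to 72 h, 887 from 72 to 96 h and 1900 from 96 to 144 h. The count against 0 h at 96 h rests on n = 1, and with the OIS 96 h columns counted as 2 samples it was 17824. The steps from 72 to 96 h and from 96 to 144 h then gave 4734 and 5866. These step counts rest on single arrays. They ranged from 91 (without OIS 48 h replicate 1) to 507, from 22 (without OIS 48 h replicate 2) to 586, from 147 (without OIS 72 h replicate 1) to 1520 and from 1097 (without OIS 144 h replicate 1) to 1990 when 1 array was left out. The 24 h count was 6156 without OIS 0 h replicate 2 and 6200 without OIS 24 h replicate 1.

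**Figure D3:**
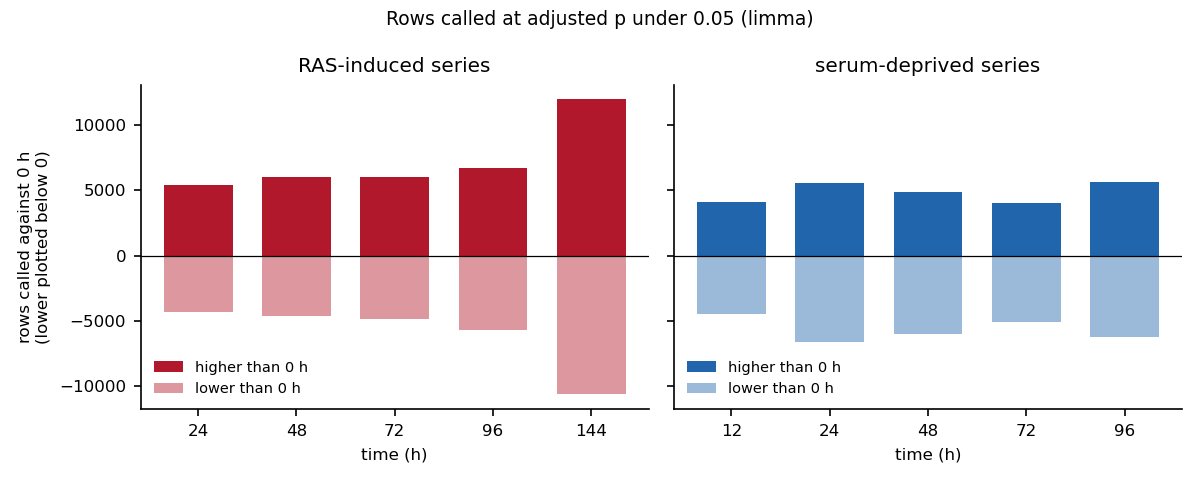
Number of rows called against 0 h at an adjusted p under 0.05 in limma, at each time (h) of the OIS series (red) and the quiescence series (blue). Rows higher than at 0 h are drawn above the axis and rows lower below it, and OIS 144 h has the most, with 11976 higher and 10615 lower.

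**Figure D4:**
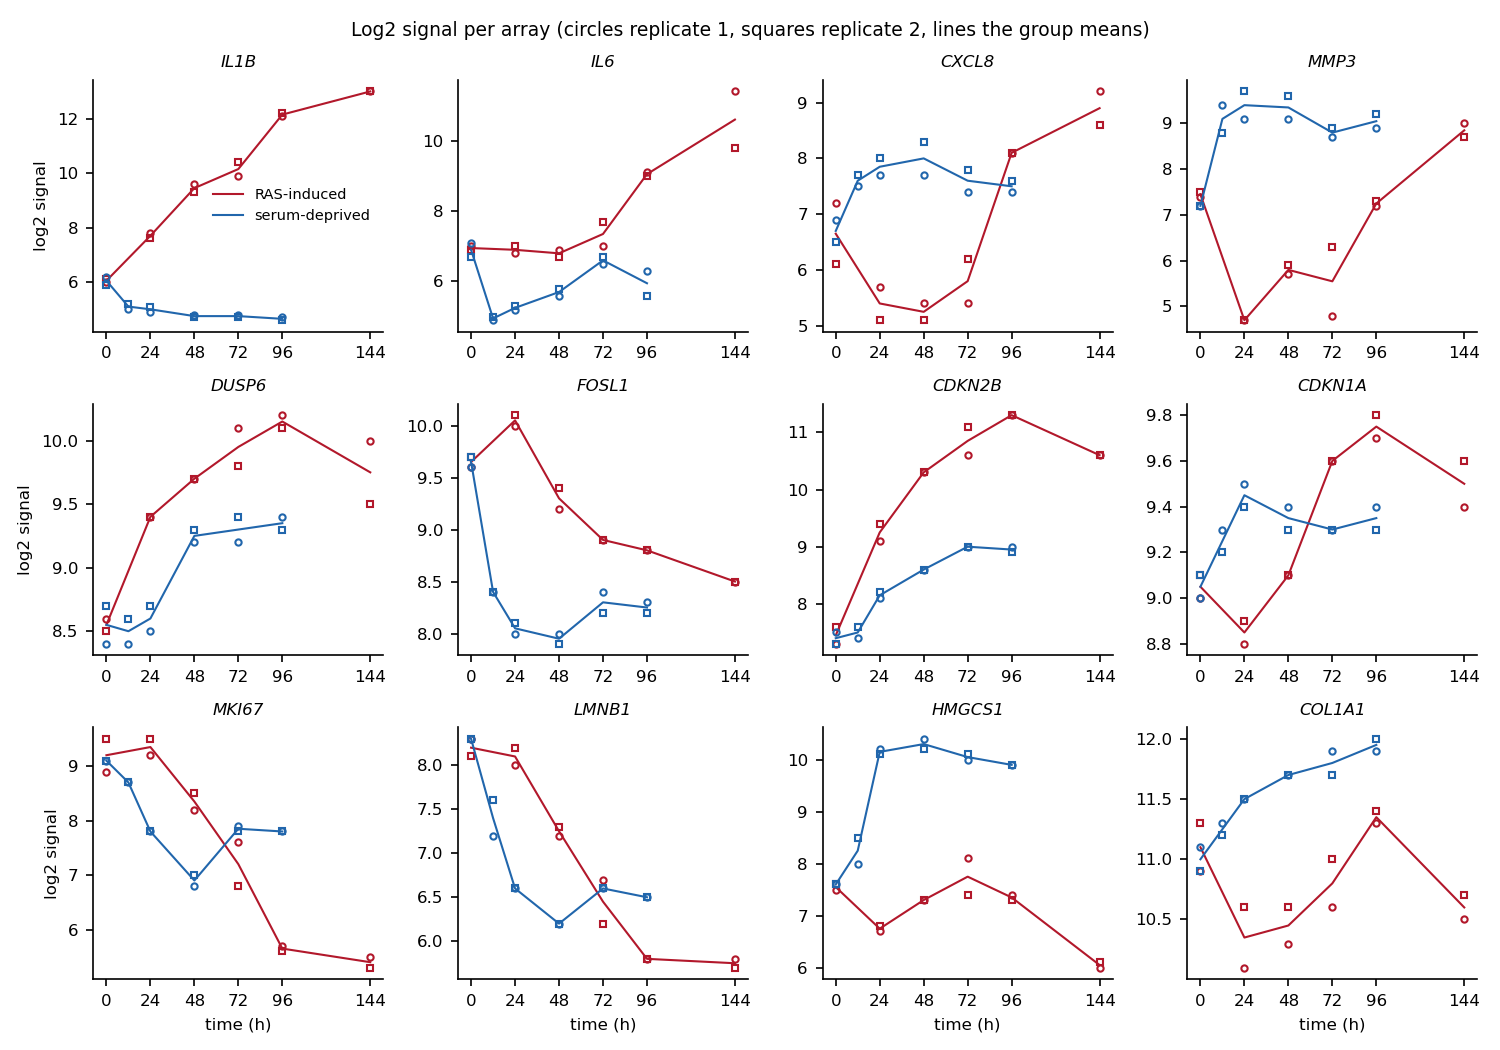
Log2 signal of 12 genes on each array (circles, replicate 1; squares, replicate 2) with group means (lines) against time in h, in the OIS series (red) and the quiescence series (blue). IL1B, at 6.05 at OIS 0 h, climbs by 6.95 in OIS and changes by -1.40 in quiescence, and the near-equal pair at OIS 96 h appears as overlapping symbols.

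After 96 h in low serum the largest rises were those of the fatty acid binding protein FABP3 (3.40 ± 0.11, SE, n = 2 arrays in each group, 10.6-fold), the oxidised LDL receptor OLR1 (3.15 ± 0.22), PLXDC2 (2.90 ± 0.30), SLITRK6 (2.75 ± 0.15), ANKRD1, a target of YAP (2.60 ± 0.19), the potassium channel KCNH1 (2.60 ± 0.11), the TNF-family ligand TNFSF18 (2.45 ± 0.09) and the galactosyltransferase B3GALT2 (2.40 ± 0.15), each with an adjusted p of 7e-06 or lower in limma. The largest falls were those of NPTX1 (-3.20 ± 0.13), HAS2 (-3.20 ± 0.29), MMP1 (-2.55 ± 0.11), LINC00707 (-2.40 ± 0.25), the small nucleolar RNA SNORD111 (-2.40 ± 0.23) and the spliceosomal U5 genes RNU5A-1 (-2.45 ± 0.28), RNU5E-1 (-2.30 ± 0.26) and RNU5D-2P (-2.60 ± 0.45), which are similar in sequence. In all, 11844 rows were called, 5605 higher and 6239 lower, and 5716 genes, 2427 higher and 3289 lower. At 2-fold or more there were 911 called rows, 399 higher and 512 lower. The count fell whichever of the 4 arrays was left out, which leaves a group with 1 array. It was 7000 without quiescence 96 h replicate 1 and lay between 7000 and 7957 when any of the 4 arrays was left out.

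The same cell cycle lists were lower in quiescence. All 39 G2/M and mitosis genes fell, with a median of -1.45 (adjusted p = 5.83e-27, adjusted p = 0.125 with an estimated correlation, 39 adjusted over the list alone), as did 33 of 35 G1/S and replication genes, with a median of -1.10 (adjusted p = 3.87e-20, adjusted p = 0.125 with an estimated correlation, 33 adjusted over the list alone). Of 29 lamina and chromatin proteins 27 fell and 1 rose, in both adjustments, including over the list alone (adjusted p = 6.01e-15, adjusted p = 0.0852 with an estimated correlation), with LMNB1 at -1.80 ± 0.14. Of 14 histone genes 12 fell (13 adjusted over the list alone, adjusted p = 4.74e-07, adjusted p = 0.0852 with an estimated correlation), and of 17 recombination and Fanconi genes 13 fell (14 adjusted over the list alone, adjusted p = 2.68e-07, adjusted p = 0.14 with an estimated correlation). MKI67 changed by -1.30 ± 0.21 and the thymidine kinase TK1 by -1.75 ± 0.11. CDKN2B rose by 1.55 ± 0.14, and CDKN2A stood at -0.10 ± 0.07 (adjusted p = 0.272).

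Sterol and matrix genes rose in quiescence. Of 19 genes of cholesterol synthesis and uptake, 18 rose and 1 fell, with a median of 1.05 (adjusted p = 5.03e-15, adjusted p = 0.125 with an estimated correlation, 18 and 1 adjusted over the list alone), led by HMGCS1 (2.30 ± 0.17), which makes HMG-CoA, and MSMO1 (1.75 ± 0.21). Of 35 collagens and matrix proteins 24 rose and 3 fell, with a median of 0.55 (adjusted p = 1.66e-08, adjusted p = 0.133 with an estimated correlation, 25 and 3 adjusted over the list alone), among them MFAP4 (1.60 ± 0.11), LUM (1.40 ± 0.16) and COL1A1 (0.95 ± 0.17). Of the 9 fibroblast markers 5 rose and 1 fell, with a median of 0.65. Of 21 contractile genes 6 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.000422, adjusted p = 0.337 with an estimated correlation), the tropomyosin TPM1 by 1.10 ± 0.12. Of 20 p53 targets 8 rose (8, with 1 falling, adjusted over the list alone, adjusted p = 0.000922, adjusted p = 0.103 with an estimated correlation), TP53INP1 by 1.30 ± 0.11. Of 20 lysosome and autophagy genes 7 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.00299, adjusted p = 0.236 with an estimated correlation). Of 22 FOXO targets and growth-arrest genes 7 rose and 3 fell (8 and 4 adjusted over the list alone, adjusted p = 0.0115, adjusted p = 0.0852 with an estimated correlation), with GABARAPL1, also an autophagy gene, up by 1.20 ± 0.11. Of 12 complement genes 5 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.0454, adjusted p = 0.236 with an estimated correlation), with C1S up by 0.95 ± 0.08.

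Most measured genes of glycolysis and of the NF-kB pathway were lower in quiescence. Of 21 glycolysis genes 15 fell and 0 rose (15 and 1 adjusted over the list alone, adjusted p = 1.14e-05, adjusted p = 0.214 with an estimated correlation), with PDK1, which restrains pyruvate oxidation, at -1.65 ± 0.13. Of 18 NF-kB pathway genes 10 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 8.48e-05, adjusted p = 0.221 with an estimated correlation), with the NF-kB inhibitor NFKBIA at -1.20 ± 0.12 and VCAM1 up by 0.90 ± 0.19. Of 24 ribosome biogenesis genes 8 fell and 0 rose (10 and 0 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.588 with an estimated correlation), with fibrillarin (FBL) at -0.75 ± 0.09. Of 19 SASP cytokines 2 rose and 7 fell (2 and 8 adjusted over the list alone, adjusted p = 0.232), with IL1B at -1.40 ± 0.15 and IL1A at -0.75 ± 0.15. Of 21 ERK targets 4 rose and 3 fell at 96 h, as they did adjusted over the list alone (adjusted p = 0.547), after 15 of 21 were lower at 12 h. The lists of AP-1 subunits, SASP proteases, SASP growth factors, CDK inhibitors, interferon-stimulated genes, Notch genes and stress response genes had camera adjusted p values from 0.437 to 0.853. In fry, SASP cytokines (downwards, adjusted p = 0.00898), ERK targets (upwards, 0.0235), SASP proteases (downwards, 0.0264) and CDK inhibitors (upwards, 0.0308) passed. FOSL1 changed by -1.40 ± 0.08 and JUN by 0.65 ± 0.11. Over time the G2/M median went from -0.45 at 12 h to -2.10 at 48 h and -1.45 at 72 h, and the cholesterol median from 0.10 at 12 h to 1.40 at 48 h. The counts of rows called were 8598 at 12 h, 12180 at 24 h, 10829 at 48 h and 9097 at 72 h, and 12927 rows changed at any time. Left-out arrays lowered them by more than 1.5 times, to 3593 at 12 h (without quiescence 12 h replicate 1; 4699 and 4877 without the 0 h arrays), 7788 at 24 h (without quiescence 24 h replicate 2), 6635 at 48 h (without quiescence 48 h replicate 2), 5420 at 72 h and 8275 at any time (both without quiescence 0 h replicate 2).

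At 96 h, the latest time of both series, the change in OIS minus the change in quiescence asks where the series differ. A difference can come from a change in either series. Of the genes named next, HAS2 was among the largest falls in quiescence. ANKRD1, OLR1, PLXDC2 and B3GALT2 were among its largest rises. The difference was largest for IL1B (7.50 ± 0.23, 181-fold; n = 1 sample at OIS 96 h and 2 arrays in each other group), HAS2 (7.45 ± 0.46), IL1A (6.60 ± 0.24), TNFSF15 (5.65 ± 0.27), SLC6A15, an amino acid transporter (5.30 ± 0.25), LCE2A (5.05 ± 0.71), FAM180A (4.50 ± 0.20) and ANGPT2 (4.40 ± 0.31). It was lowest for ANKRD1 (-5.40 ± 0.30), OLR1 (-5.35 ± 0.34), the growth factor TGFB2 (-5.20 ± 0.38), B3GALT2 (-4.30 ± 0.24), the aggrecanase ADAMTS5 (-3.80 ± 0.19), PLXDC2 (-3.55 ± 0.47), the platelet-derived growth factor PDGFD (-3.50 ± 0.26) and the matrix protein EFEMP1 (-3.45 ± 0.38). All had an adjusted p of 0.000101 or lower in limma. In all, 13679 rows differed, 7437 with a positive and 6242 with a negative difference (6623 and 6639 under the other quantile normalization), and 6351 genes, 3893 and 2458. With the last points of both series, 144 and 96 h, 19327 rows differed.

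Of 21 ERK feedback and target genes, 15 had a positive difference at 96 h and 2 a negative one, with a median of 0.80 (adjusted p = 1.87e-05, adjusted p = 0.0384 with an estimated correlation, 17 and 2 adjusted over the list alone). SPRY2, a feedback inhibitor of the pathway, differed by 2.35 ± 0.24. Of these 21 genes 2 are also in other lists, among them LIF in that of the SASP cytokines. Of 19 SASP cytokines 13 differed upwards and 2 downwards (13 and 2 adjusted over the list alone, adjusted p = 6e-06, adjusted p = 0.0852 with an estimated correlation), with IL6 at 3.05 ± 0.58 and CXCL8 at 0.65 ± 0.55 (adjusted p = 0.39). Of 21 glycolysis genes 17 differed upwards and 0 downwards, in both adjustments, including over the list alone (adjusted p = 1.65e-06, adjusted p = 0.172 with an estimated correlation), with PDK1 at 2.35 ± 0.21. Of 18 NF-kB genes 11 differed upwards and 1 downwards (13 and 2 adjusted over the list alone, adjusted p = 5.08e-05, adjusted p = 0.214 with an estimated correlation). Of 24 ribosome biogenesis genes 13 differed upwards and 0 downwards, also adjusted over the list alone (adjusted p = 0.000698, adjusted p = 0.337 with an estimated correlation). CDKN2B differed by 2.30 ± 0.22 and MMP1 by 2.75 ± 0.18. The MMP1 difference came mainly from quiescence, with a change of 0.20 in OIS and -2.55 in quiescence.

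Matrix, contractile and sterol genes had negative differences. The sterol list had a median change of 1.05 and a mean change of 1.10 at quiescence 96 h, and a mean difference of -0.753. On average it was therefore higher than at 0 h in OIS at 96 h too, by less than in quiescence. At the later OIS time of 144 h its median change was 0.05. For collagens and matrix proteins the numbers were 23 downwards and 4 upwards of 35 (25 and 5 adjusted over the list alone, adjusted p = 3.33e-08, adjusted p = 0.14 with an estimated correlation), with the proteoglycan LUM at -3.20 ± 0.26. For contractile genes they were 14 and 0 of 21 (17 and 0 adjusted over the list alone, adjusted p = 2.19e-09, adjusted p = 0.133 with an estimated correlation), with CCN2 at -2.45 ± 0.28. For cholesterol genes they were 14 and 1 of 19 (15 and 1 adjusted over the list alone, adjusted p = 3.33e-06, adjusted p = 0.289 with an estimated correlation), with the isomerase IDI1 at -1.55 ± 0.25. For FOXO targets they were 9 and 3 of 22, also adjusted over the list alone (adjusted p = 0.0116, adjusted p = 0.0852 with an estimated correlation), and TXNIP differed by 1.40 ± 0.15. For complement genes they were 4 and 2 of 12, also adjusted over the list alone (adjusted p = 0.0191, adjusted p = 0.194 with an estimated correlation), with C1S at -2.05 ± 0.13.

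Mitotic genes were lower in OIS than in quiescence at 96 h. Of 39 G2/M genes 29 had a negative difference and 1 a positive one, with a median of -1.05 (30 and 2 adjusted over the list alone, adjusted p = 3.4e-11, adjusted p = 0.293 with an estimated correlation), and MKI67 differed by -2.25 ± 0.34. At 24 h the same list differed the other way, with 36 of 39 genes higher in OIS and a median of 1.60. At 96 h, 9 of 17 recombination genes (10 adjusted over the list alone, adjusted p = 3.41e-05, adjusted p = 0.221 with an estimated correlation), 7 of 35 replication genes, against 3 upwards (7 and 3 adjusted over the list alone, adjusted p = 0.00872, adjusted p = 0.681 with an estimated correlation, 0.18 in fry), and 6 of 14 histone genes, against 2 upwards (7 and 2 adjusted over the list alone, adjusted p = 0.0396, adjusted p = 0.337 with an estimated correlation), had negative differences. LMNB1 differed by -0.60 ± 0.22 (adjusted p = 0.0476), a call lost without OIS 0 h replicate 1 (-0.50) or without any of the 4 quiescence arrays at 0 and 96 h (-0.60 each, adjusted p from 0.0888 to 0.0933). The lists of RAS genes (HRAS alone, 0.00 ± 0.10), AP-1 subunits, SASP proteases, SASP growth factors, CDK inhibitors, p53 targets, lamina and chromatin proteins, interferon-stimulated genes, Notch genes, stress response genes and lysosome genes did not pass in camera, with adjusted p from 0.165 to 0.891. In fry, SASP proteases (adjusted p = 0.000629), p53 targets (0.000666), CDK inhibitors (0.000991) and SASP growth factors (0.00228) passed, all upwards. Median, mean and test differ in sign for the AP-1 list at 144 h and in the difference (medians 0.00, means 0.06 and 0.04, test downwards), and in quiescence for the CDK inhibitors (median -0.075, mean 0.23), SASP proteases and interferon genes, and for the lysosome list in the difference (median 0.025, mean -0.02). None of these lists passed there in camera.

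**Figure D5:**
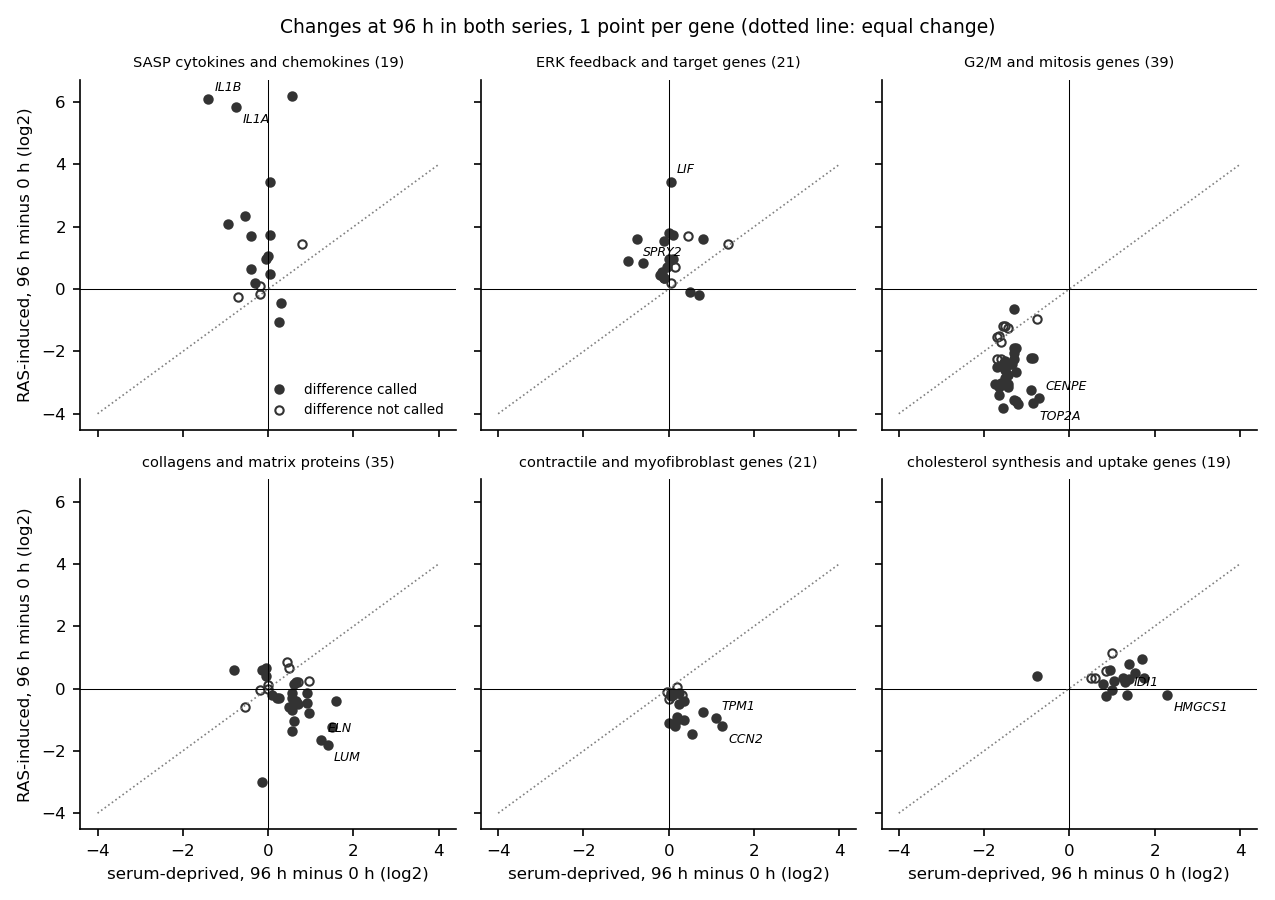
Log2 change at 96 h in OIS (vertical axis) against quiescence (horizontal axis) for the members of 6 gene lists, 1 point per gene, filled where the difference was called. The dotted line marks equal change, and the 2 genes with the largest difference in each list are named, such as IL1B at 6.10 in OIS and -1.40 in quiescence.

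At 96 h 8467 rows were OIS-specific, 4709 higher and 3758 lower (4033 and 4022 under the other quantile normalization), among them 4205 genes. Of these rows, 2975 of the higher and 2094 of the lower were not called in quiescence, 1572 and 1376 were called there in the opposite direction, and the rest were called in the same direction and also count as shared. Called in the same direction in both series were 2084 rows, 904 higher, against 910.1 for independent lists of these sizes, and 1180 lower, against 857. Over genes, 561 were higher in both, against 508.7, and 759 lower, against 473.1. Across rows the changes of the series had r = -0.0426 and rho = -0.115, and across genes r = 0.0963. The covariance was -0.00683, against 0.00728 from the spread of the 0 h means alone if both series shared 1 baseline, which the counts for independent lists leave out. Rows and genes are not independent replicates. The shared count was 1378 without quiescence 96 h replicate 2. At 0 h the series, which have separate arrays, differed in 0 rows in limma, and 0 of 41249 rows had an unadjusted p under 0.05. The SD over rows of the difference between the 0 h means was 0.0525, against 0.127 from the spread within the groups, so the starting points were closer than their replicates.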

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

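The tests on the near-equal columns at OIS 96 h and on the close 0 h means were all chosen after the result was seen. The results that follow were noted because the changes at 96 h went in opposite directions in the 2 series and the difference itself passed its test. IL1B stood at 6.10 in OIS and -1.40 in quiescence, a difference of 7.50 (adjusted p = 2.16e-10 in limma), and IL1A at 5.85 and -0.75, a difference of 6.60 (adjusted p = 1.31e-09). The median of the SASP cytokines was 1.05 in OIS and -0.20 in quiescence, with a difference of 1.05 (camera adjusted p = 6e-06, adjusted p = 0.0852 with an estimated correlation), and that of the NF-kB pathway genes 0.325 and -0.325, with a difference of 0.775 (adjusted p = 5.08e-05, adjusted p = 0.214 with an estimated correlation). For the glycolysis genes the medians were 0.35 and -0.40, with a difference of 0.60 (adjusted p = 1.65e-06, adjusted p = 0.172 with an estimated correlation), and for the ribosome biogenesis genes 0.225 and -0.15, with a difference of 0.325 (adjusted p = 0.000698, adjusted p = 0.337 with an estimated correlation).

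The matrix and contractile lists went the other way. The median of the collagens and matrix proteins was -0.30 in OIS and 0.55 in quiescence, with a difference of -0.70 (adjusted p = 3.33e-08, adjusted p = 0.14 with an estimated correlation), and that of the contractile genes -0.40 and 0.20, with a difference of -0.75 (adjusted p = 2.19e-09, adjusted p = 0.133 with an estimated correlation). For the FOXO targets and growth-arrest genes the medians were -0.175 and 0.10, with a difference of -0.125 (adjusted p = 0.0116, adjusted p = 0.0852 with an estimated correlation). The difference of a list is the median of its members' differences. OIS 96 h counts as n = 1 in each of these.

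The OIS 96 h columns differ less than any other pair. A single set of values written to both columns would make every row equal, and is argued against by the 77.2% of rows that are equal. The SD of 0.0486 lies below the lowest of the other pairs (0.119). That closeness is what drew attention to the pair, so it is no separate test of 2 cultures handled like every other group. The small differences between the columns run parallel to those between replicates at the other OIS times, with a lowest correlation of 0.143. This argues against 1 RNA measured 2 times with unrelated differences. It does not argue against 1 RNA measured 2 times with differences that follow the replicate number. The slope of the column differences on the mean replicate difference of the other times is 0.193. A row-by-row adjustment of the columns before deposit may have shrunk a replicate difference. This adjustment and a repeat measurement of the second kind stay open. No biological explanation was tested, and the mean of these columns gave the values at OIS 96 h.

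The 0 h means of the series also lie closer than replicates do. The deviations of the OIS 0 h arrays from the quiescence 0 h mean correlate at -0.662, where independent arrays would correlate at 0 or above. Means this close make such a correlation negative, so it restates the closeness and is no separate test. The SD of the difference between the means of the real pairs is 0.0525. The lower of the other splits of these 4 arrays is larger by a ratio of 2.36. The largest ratio between the SDs of the replicate pairs of the 11 groups apart from OIS 96 h is 1.71. Pairs of different groups are not splits of the same arrays, and the ratio of 2.36 holds the same closeness of means. It therefore does not decide whether 1 set of cultures was sampled for both series. The deviations of the quiescence 0 h arrays from the OIS mean correlate at -0.35, which restates the closeness as well. A row-by-row adjustment that aligned the series at 0 h may explain the close means. That adjustment stays open, no biological explanation was tested, and a comparison of the series at 0 h from these values cannot show how alike the cultures were. An adjustment of this kind could also change the spread and the 0 h means that enter every comparison. The p-values and counts in all sections take the values as deposited and do not allow for it.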

How the results depend on the processing

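Chosen after the data were seen were the settings with all 24 arrays, with identical rows counted once and with 72 h in place of 96 h. For OIS 144 h against 0 h the count of 22591 went to 2806 at 2-fold or more, 2909 with treat against 1.5-fold and 10165 with 1 row per gene. For quiescence 96 h the count of 11844 went to 6735 at an adjusted p under 0.01, 911 at 2-fold or more, 607 with treat and 5716 with 1 row per gene. For the difference at 96 h the count of 13679 went to 8170, 3012, 1608 and 6351 under the same 4 settings. Stricter thresholds, and fewer rows in the last of these, lower the counts by construction. The other normalization, median centring, dim rows left out, the intensity trend, array weights, all 24 arrays and identical rows counted once kept these 3 counts within 1.5 times, as did the arrays of 1 series alone for the first 2. The shared count of 2084 became 1236 with 72 h in place of 96 h. The cause was not tested.

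Leaving out 1 array at a time leaves a group with 1 array, assumed to vary like the other groups. The counts then ranged from 7000 to 7957 for quiescence 96 h, from 8275 to 12320 for quiescence at any time, from 1378 to 2107 for shared rows and from 6156 to 8226 for OIS 24 h. For quiescence at 12, 24, 48 and 72 h the ranges were 3593 to 6720, 7788 to 8327, 6635 to 7563 and 5420 to 5593. For the steps from 24 to 48 h, 48 to 72 h, 72 to 96 h and 96 to 144 h they were 91 to 507, 22 to 586, 147 to 1520 and 1097 to 1990. Counts for OIS 144 h (18761 to 19422), the difference at 96 h (10797 to 13725) and OIS-specific rows (7013 to 8556) stayed within 1.5 times. Counting the near-equal OIS 96 h columns as 2 samples gave 4734 rows for the step from 72 to 96 h and 5866 for the step from 96 to 144 h. The cause was not tested.

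With the replicate number as a block, the counts were 1225, 618 and 1618 for the first 3 steps, and 23417, 13236 and 14884 for OIS 144 h, quiescence 96 h and the difference. The differences between replicates correlated at 0.144 to 0.451 in 10 of 10 pairs of OIS times, and in quiescence had a median correlation of 0.00701, with 2 of 15 over 0.1. Between the series the median was -0.00653, with 4 of 30 over 0.1. The highest of all, 0.502, was between quiescence 96 h and OIS 144 h, so such correlations were not confined to the OIS series. The labels do not say that replicate numbers pair the arrays across times.

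Of 75 tests of gene lists, 41 passed in camera, 1 with a correlation estimated for each list, 39 with the block, 56 in fry and 72 in fry for mixed directions. No called value of a named gene changed sign under the alternatives in the next sentence, and fry gave the camera direction for each list that camera called. Which direction had more rows did change. For the difference at 96 h, 7437 higher and 6242 lower became 6623 and 6639 under the other quantile normalization and 1468 and 1544 at 2-fold or more, and for OIS 144 h, 11976 and 10615 became 1329 and 1477 at 2-fold or more. Of 350 values of named genes, 3 lost and 1 gained their call under the other quantile normalization, 1 lost it under median centring, 3 gained it with array weights, and 33 lost and 3 gained it when some array was left out. The scaling alternatives moved the median of all rows by -0.05 at most. The number of arrays limits the precision, and dim rows (log2 under 5.7 in every group) carry the least signal over background.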

Other observations

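The families below were formed from gene symbols, and they and the test of ribosome biogenesis against small nucleolar RNA were chosen after results were seen. In OIS at 144 h, 12 of 17 genes of the late cornified envelope (LCE) family were higher and 0 lower (median 0.35, camera adjusted p = 0.00721, adjusted p = 0.878 with an estimated correlation). So were 14 of 18 genes named for the Integrator complex, which processes small nuclear RNA, pseudogenes and a paralogue included (INTS, 0.35, adjusted p = 0.00555, adjusted p = 0.876 with an estimated correlation), and 14 of 19 histone demethylases (KDM, 0.50, adjusted p = 0.01, adjusted p = 0.876 with an estimated correlation), with 1 KDM gene lower. Lower were 14 of 16 nucleosome-binding HMGN rows, many of them retrocopies of similar sequence (-0.775, adjusted p = 0.000183, adjusted p = 0.876 with an estimated correlation), and 6 of 8 of the HNRNPA family of RNA-binding proteins (-1.02, adjusted p = 0.00191, adjusted p = 0.878 with an estimated correlation). In the difference at 96 h, 29 of 50 mitochondrial ribosomal proteins (MRPL, 0.40, adjusted p = 0.000153, adjusted p = 0.878 with an estimated correlation) and 9 of 11 proteasome subunits (PSMB, 0.55, adjusted p = 0.0171, adjusted p = 0.878 with an estimated correlation) were higher in OIS. In quiescence at 96 h, 13 of 22 nucleoporins (NUP, -0.40, adjusted p = 0.000587, adjusted p = 0.876 with an estimated correlation) were lower. Of 1256 tests, over 314 families in 4 comparisons, 56 passed and 0 passed with an estimated correlation.

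Rows named for small nucleolar RNA, which guides the modification of ribosomal RNA, had positive medians in OIS and negative medians in quiescence. Of 178 such genes, 109 were higher and 7 lower after 24 h of OIS (median 0.60, adjusted p = 1e-17, adjusted p = 0.0573 with an estimated correlation) and 57 higher and 28 lower at 144 h (0.15, adjusted p = 0.564). In quiescence 74 were lower and 3 higher at 12 h (-0.40), and 80 lower and 11 higher at 96 h (-0.35, adjusted p = 2.34e-05, adjusted p = 0.218 with an estimated correlation). In the difference at 96 h the median was 0.775 (adjusted p = 1.73e-07, adjusted p = 0.148 with an estimated correlation). Within this class, 46 of 59 SNORA genes were higher at OIS 24 h (0.80) and 43 lower at quiescence 96 h (-0.70). Of 117 SNORD genes 62 were higher and 5 lower at OIS 24 h (0.50), and 35 were lower and 10 higher at quiescence 96 h, with a median of only -0.10. The pattern is not particular to nucleolar RNA. Of 22 small nuclear RNA genes 13 were higher and 0 lower at OIS 24 h (0.525, adjusted p = 4.93e-05, adjusted p = 0.0871 with an estimated correlation), and 14 lower and 0 higher at quiescence 96 h (-0.55, adjusted p = 9.18e-06, adjusted p = 0.0678 with an estimated correlation). Of 16 small Cajal body RNA genes (SCARNA) 11 were higher and 0 lower at OIS 24 h (0.40, adjusted p = 0.000107, adjusted p = 0.0871 with an estimated correlation), and 11 lower and 1 higher at quiescence 96 h (-0.525, adjusted p = 0.000295, adjusted p = 0.0969 with an estimated correlation).

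A shift that depends on signal level would put the quiescence median of -0.35 among those of 10000 random sets matched on signal, and it lay at percentile 0, outside their range of -0.10 to 0.05. These sets were drawn gene by gene, whereas the estimated correlation within the class was 0.114. The percentile therefore does not show how often a correlated class would reach such a median. A loss during extraction that grows as RNA gets shorter would lower shorter ones more. The correlation of change with length was rho = -0.497 (153 genes, 60 to 237 bases), with a permutation p of 1e-04, the smallest these permutations can give. The permutations treat these genes as independent. At OIS 24 h rho was 0.356, so longer ones tended to rise more there. SNORA and SNORD genes, whose medians differ, were not separated in these correlations. A loss of the whole class alike is not tested by a correlation within the class and stays open. How much RNA of this length the column kit kept was not measured here. Mature small RNA was not told apart from its precursors. The medians of small nucleolar RNA had the same sign as those of the ribosome biogenesis list in 10 of 10 comparisons with 0 h. These comparisons share the 0 h arrays of each series, and with 2 series the signs would match in both with a chance of 0.25, so this does not decide whether the change goes in step with ribosome biogenesis. That explanation stays open, and host gene transcription was not tested.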
